A study of Mus musculus with 6 samples.

How the data were processed

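CD11c+ spleen cells of untreated mice from 3 fate-mapping lines were read by droplet single-cell RNA sequencing, with 1 library per line and 3 mice per line in each library, marked by hashtag antibodies. The deposited files hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 per the file headers and against build mm10 per the submitters' processing notes. The annotation release, the use of strand in counting and the filter on barcodes are not given in the sources used here. Each matrix lists 32285 genes, the sequences of tdTomato, human CD2, iCre and a further Cre, and 3 hashtags, and 32158 of the 32285 gene IDs were found in GENCODE vM21, from which coordinates are given. Antisense genes, overlapping genes and near-identical gene families, such as haemoglobin, Ly49 receptor, MHC and immunoglobulin genes and Cd300c with Cd300c2, are uncertain, since their reads can be shared.

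The 3 libraries held 30724, 31630 and 33901 barcodes (CD300c-iCre, IL-7R-Cre and Ms4a3-Cre line), with 391220847, 392516248 and 363730706 UMIs. Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept (29237, 29997 and 32097). HTODemux of Seurat 5.3.0 (positive quantile 0.99) called 4803, 5169 and 4400 of them hashtag doublets (16.4%, 17.2% and 13.7%) and 933, 1642 and 4340 without a hashtag, which were left out with the cells marked by Scrublet (2304, 3438 and 4736, or 9.80%, 14.8% and 20.3% of the single cells). Scrublet also marked 65.8%, 72.5% and 75.6% of the hashtag doublets. The labels give mice as the samples within a line, so each mouse was counted as 1 replicate, and p-values measure the spread between them. A check for samples that agree within counting noise found none (chi-square per degree of freedom of 2.03 to 22.0 over 27 comparisons). These took the same pairs of mice in cDC2-, cDC1- and pDC-like cells.

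Counts were scaled to 10000 per cell and logged, and each gene was centred within its library. With scanpy 1.11.5, 2000 variable genes, leaving out driver, reporter and sex-linked genes, gave 30 principal components, a graph of 20 neighbours and 34 Leiden clusters (leidenalg 0.10.2, resolution 1, seed 1). A cluster took the class whose fixed markers it held most above the other clusters, with a score of at least 0.8 for DC classes and 2 for others, thresholds that were set after the data were seen, and "-like" marks such names. The cDC2-like class joins clusters 1, 4, 5 and 21 (cDC2A-like) and 2 and 13 (cDC2B/DC3-like). No cDC2 marker was among the 10 leading genes of cluster 1, which Il1r2 and Ptgs2 led, and interferon-induced genes such as Ifit3 led cluster 21. A cell was tdTomato-positive with at least 1 UMI, and shares are over cells thinned to 3000 UMIs without replacement.

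Shares were compared over the 9 mice by an exact permutation test of the sum of squares between lines, over all 1680 assignments, two-sided by construction, adjusted by Benjamini-Hochberg over the classes. Its smallest p is 0.00357, while 3 mice against 3 could not go below 0.1, so no pair of lines was tested in this way. For genes, counts were summed per mouse and class, filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, Benjamini-Hochberg over all genes tested), in 1 fit of the 9 mice for the comparisons of lines. The fit of positive against negative cells had a term per mouse, a tdTomato term per line, and left tdTomato itself out. CPM beside a fold change are scaled by TMM, and other CPM are plain. An adjusted p at or under 0.05 was taken as passing. The 33 fixed gene lists were tested with camera at a preset correlation of 0.01, with an estimated one, and with fry (limma 3.58.1), each in the same design and adjusted over the lists.

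The genes named are the up to 10 higher and 10 lower ones of a comparison with the largest fold change among those passing, at 20 CPM or more, with a gene symbol other than a clone name and the same direction in each mouse, then up to 4 genes per list by smallest p, and the driver and reporter genes. The text names at most 2 genes per list, a limit set after the data were seen, and of these it names a part. The groups, tests, lists, markers, naming rule and most alternatives were chosen before the data were examined. The gene tests were tested on simulated counts with 200 changed genes. Each gene was drawn on its own, without the variation between mice that genes share in these data. The shares found and false calls therefore do not show how the tests behave under such variation. For the CD300c-iCre against the Ms4a3-Cre line in cDC2-like cells (13185 genes) 68.7%, 82.1% and 98.5% of genes changed by 1.5, 2 and 4 fold were found with 11 false calls, in cDC1-like cells (12030 genes) 61.2%, 77.6% and 95.5% with 13, and in pDC-like cells (12031 genes) 55.2%, 76.1% and 98.5% with 4. For positive against negative cDC2-like cells of the CD300c-iCre line (12519 genes) the shares were 61.2%, 77.6% and 97.0% with 4 false calls, and for cDC1-like cells (11326 genes) 71.6%, 95.5% and 100% with 7.

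Alternatives were other hashtag, doublet and cell filters, clustering without centring or at resolutions 0.5 and 2, other tdTomato thresholds, no thinning, DESeq2 1.42.0 as test or for size factors, no gene filter, blocks, equal cell numbers, single subclasses and leaving out each mouse. Of the genes in the lists, Mx1, Clec7a and Aldoa were not analysed here. R 4.3.3 and Python 3.11.15 were used.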

Results

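Single-cell transcriptomes of CD11c+ spleen cells, the fraction that holds most splenic dendritic cells (DC), were read in 3 mouse lines. Each line carried Cre recombinase at a gene of haematopoietic cells together with a reporter at the Rosa26 locus. The labels give the mice as heterozygous for both. The reporter makes the red fluorescent protein tdTomato in every cell that has expressed Cre and in its progeny. In the CD300c-iCre line, which also carried human CD2, Cre was tied to Cd300c, a gene of the CD300 receptor family (ENSMUSG00000058728, chromosome 11, 114956116 to 114969157, minus strand, mm10). In the IL-7R-Cre line it was tied to Il7r, the receptor of the lymphoid growth factor interleukin 7 (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, minus strand). In the Ms4a3-Cre line it was tied to Ms4a3, a gene of granulocyte-monocyte progenitors (ENSMUSG00000024681, chromosome 19, 11629496 to 11640851, minus strand). Each line was read as 1 library holding 3 mice told apart by hashtag antibodies. The mouse was the replicate (n = 3 per line, 9 in all), while line and library could not be told apart. After filtering, 21197 cells of the CD300c-iCre line, 19748 of the IL-7R-Cre line and 18621 of the Ms4a3-Cre line were kept. Each mouse gave 4758 to 7583 cells and 48225133 to 83692999 UMIs (molecules counted). Median UMIs per cell were 9726, 9674 and 8405 in the 3 lines.

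Clusters named by marker lists gave 20517 cDC2-like, 11368 pDC-like (plasmacytoid), 8403 cDC1-like, 2854 mature DC-like and 2584 transitional DC-like cells. Beside these there were 3443 NK cell-like, 2747 T cell-like, 841 B cell-like, 759 non-classical monocyte-like, 509 red pulp macrophage-like and 2551 proliferating cells. The lines ask which progenitors contribute to cDC2, the conventional DC that present antigen on MHC class II to CD4 T cells. cDC2-like cells made up 35.5% ± 7.08 (SD, n = 3 mice) of the CD300c-iCre line, 33.3% ± 7.41 of the IL-7R-Cre line and 34.4% ± 3.18 of the Ms4a3-Cre line. The pDC-like share was 20.7% ± 7.20, 20.8% ± 12.0 and 16.1% ± 3.27 in the same order. The cDC1-like share was 15.4% ± 2.47, 13.8% ± 1.35 and 13.1% ± 0.603. T cell-like cells were 3.05% ± 0.146, 3.92% ± 0.528 and 6.68% ± 3.28. They were the 1 class of 11 past the threshold (two-sided exact permutation test over 1680 assignments of the mice, p = 0.00357, the smallest possible, adjusted p = 0.0393). The share no longer passed without any 1 mouse of the CD300c-iCre or IL-7R-Cre line. NK cell-like cells were 2.60% ± 0.621, 5.49% ± 2.02 and 9.86% ± 5.62 (exact permutation p = 0.0750, adjusted p = 0.327). The CD11c+ sort can set these shares, and 4.44%, 6.68% and 3.71% of the cells of the 3 lines stayed unnamed.

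tdTomato marked most pDC-like cells in the CD300c-iCre and IL-7R-Cre lines and non-classical monocyte-like cells in the Ms4a3-Cre line. With each cell thinned to 3000 UMIs, at least 1 tdTomato UMI was found in 75.2% ± 1.81 of pDC-like cells of the CD300c-iCre line (n = 3 mice), 72.1% ± 2.23 in the IL-7R-Cre line and 25.7% ± 0.806 in the Ms4a3-Cre line. For cDC2-like cells the shares were 61.2% ± 1.90, 30.4% ± 0.802 and 13.7% ± 0.885. cDC1-like cells, specialised in cross-presentation, had shares of 22.0% ± 1.2, 17.4% ± 3.07 and 9.34% ± 1.26. Transitional DC-like cells, which share genes of pDC and cDC2, followed the order of cDC2 at 62.2% ± 2.41, 42.9% ± 3.96 and 13.2% ± 2.67. Mature DC-like cells, marked by the migration receptor Ccr7, stood at 52.9% ± 4.42, 41.5% ± 2.15 and 8.54% ± 2.00. They pool cluster 9 (64.7%, 50.1% and 9.05%) and cluster 18 (26%, 19.0% and 7.24%). The order was another one in cells outside the DC lineage. T cell-like cells were positive in 15.2% ± 2.39, 60.4% ± 0.172 and 9.59% ± 1.48. NK cell-like cells were positive in 15.4% ± 4.32, 72.8% ± 2.34 and 12.4% ± 0.669, and non-classical monocyte-like cells in 11.5% ± 1.39, 12.8% ± 4.91 and 57.7% ± 4.71. All 9 classes with at least 20 cells per mouse differed between the lines (two-sided exact permutation test, p = 0.00357 and adjusted p = 0.00459 in 7 of them, p = 0.0143 in NK cell-like and p = 0.0321 in non-classical monocyte-like cells).

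**Figure D1:**
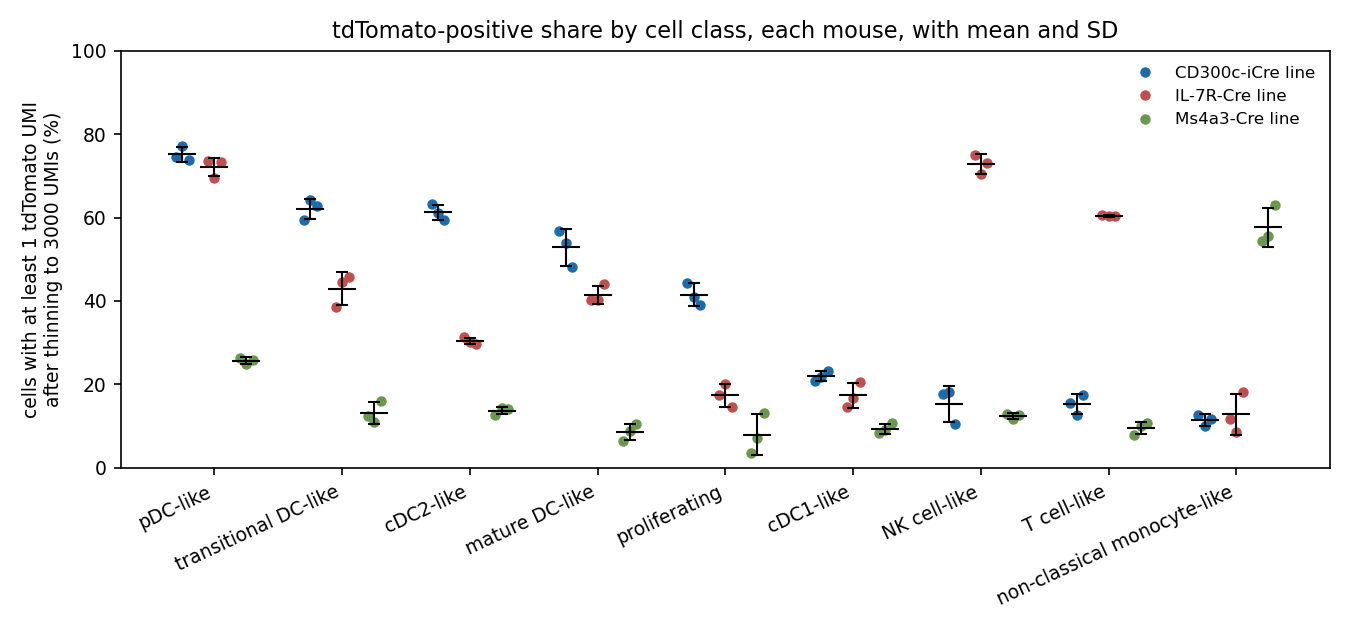
Percent of cells with at least 1 tdTomato UMI after thinning to 3000 UMIs (vertical axis) in each cell class (horizontal axis), with 1 point per mouse and the mean and SD of the 3 mice of each line. pDC-like cells reach 75.2% and 72.1% in the CD300c-iCre and IL-7R-Cre lines, and non-classical monocyte-like cells reach 57.7% in the Ms4a3-Cre line.

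Free RNA in droplets gives some UMIs in cells that do not express a gene. T cell-like cells of the CD300c-iCre line (15.2%, median 7353 UMIs, against 9550 UMIs in cDC2-like cells) and of the Ms4a3-Cre line (9.59%, 5771 against 8776 UMIs) were taken as that background. In the IL-7R-Cre line, non-classical monocyte-like cells took this place (12.8%, 5923 against 9833 UMIs). In this share at 1 UMI, cDC1-, transitional and mature DC-like cells of the Ms4a3-Cre line, at 8.54% to 13.2%, lay close to the background. cDC2-like cells there stood little above it. At 2 or more UMIs after thinning, 3.75% ± 0.344 of cDC2-like cells there were positive against 0.566% ± 0.507 of T cell-like cells. cDC1-, transitional and mature DC-like cells had 1.44% ± 0.587, 1.94% ± 1.69 and 1.94% ± 0.395. The classes differ in depth, so a close share at 1 UMI does not show that these cells are unlabelled. Thinning left out 1126, 1267 and 1400 shallower cells. Without it the cDC2-like shares were 77.4% ± 2.56, 48.8% ± 1.16 and 26% ± 0.618, and the pDC-like shares 95.5% ± 0.327, 95.1% ± 0.341 and 54.7% ± 2.81. The tdTomato level went the same way, at 452 ± 6.68, 183 ± 13.7 and 60.9 ± 5.81 CPM (counts scaled to the same total) in cDC2-like cells. pDC-like cells held 502 ± 15.6, 443 ± 26.2 and 99.6 ± 6.51 CPM. The T cell-like background was 43.3 ± 7.68 CPM in the CD300c-iCre line and 32.8 ± 5.96 CPM in the Ms4a3-Cre line.

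Within cDC2, the CD300c-iCre and IL-7R-Cre lines marked cDC2A-like cells, the Notch-dependent subset, more often than cDC2B/DC3-like cells, which share genes with monocytes. The Ms4a3-Cre line did the opposite. In the CD300c-iCre line the lower share came with the DC3 cluster of the cDC2B/DC3-like class (cluster 2, 31.1% ± 4.12). Its cDC2B cluster (cluster 13, 56.2% ± 7.28) stood at the level of the lowest cDC2A-like cluster (cluster 5, 56.0% ± 2.43). The cDC2A-like share was 69.6% ± 0.963, 36.8% ± 0.280 and 9.60% ± 0.736 in the CD300c-iCre, IL-7R-Cre and Ms4a3-Cre lines (n = 3 mice each). The cDC2B/DC3-like share was 35.9% ± 4.30, 17.7% ± 1.76 and 22.5% ± 2.30. The difference within each mouse was 33.7 ± 3.86, 19.1 ± 1.49 and -12.9 ± 1.97 percentage points. It differed between the lines (two-sided exact permutation test, p = 0.00357, the smallest possible). cDC2A-like cells of the Ms4a3-Cre line were at the level of the T cell-like background of 9.59%. Unthinned, the cDC2A-like shares were 85.0% ± 1.55, 53.9% ± 0.506 and 20.9% ± 0.701. The cDC2B/DC3-like shares were then 54.1% ± 4.83, 38.4% ± 2.24 and 37.4% ± 1.63. In the tdTomato level, cDC2A-like cells held 529 ± 11.1, 234 ± 8.74 and 34.9 ± 4.84 CPM. cDC2B/DC3-like cells held 231 ± 27.3, 86.9 ± 3.53 and 115 ± 14.9 CPM.

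**Figure D2:**
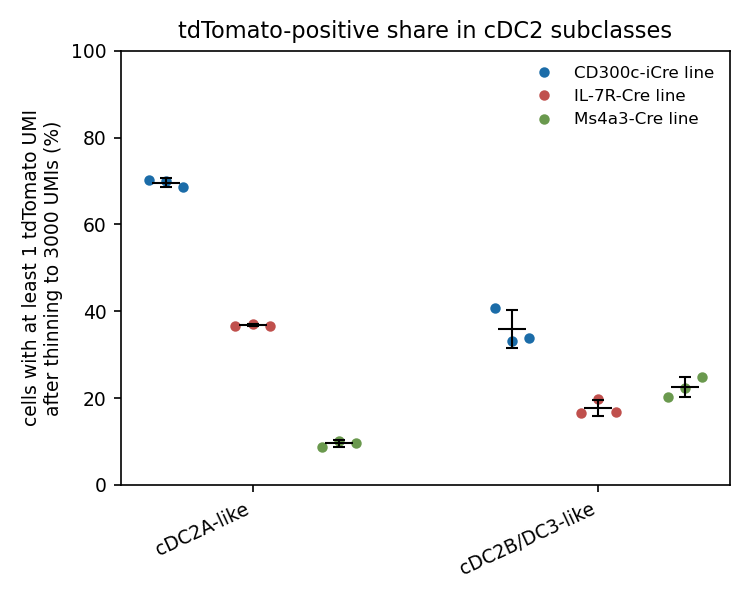
Percent of cells with at least 1 tdTomato UMI after thinning to 3000 UMIs (vertical axis) in cDC2A-like and cDC2B/DC3-like cells (horizontal axis). Colours mark the 3 lines, with 1 point per mouse and the mean and SD of 3 mice. cDC2A-like cells lie above cDC2B/DC3-like cells in the CD300c-iCre line (69.6% against 35.9%) and the IL-7R-Cre line, and below them in the Ms4a3-Cre line (9.60% against 22.5%).

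The transcripts of the driver constructs differed by line. Human CD2 was counted in the CD300c-iCre line alone, at 69.0 ± 2.18 CPM in pDC-like cells, 24.6 ± 4.31 CPM in transitional DC-like, 3.34 ± 0.456 CPM in cDC1-like and 1.36 ± 0.186 CPM in cDC2-like cells, beside 1.09 ± 1.88 CPM in non-classical monocyte-like and 0 UMIs in T cell-like cells. The improved Cre (iCre) sequence was counted in the IL-7R-Cre line at 169 ± 39.9 CPM in T cell-like, 86.5 ± 16.9 CPM in pDC-like and 47.2 ± 17.2 CPM in NK cell-like cells. The 1.26 ± 0.108 CPM in cDC2-like cells lay below the 3.11 ± 0.751 CPM of non-classical monocyte-like cells, the background class of that line. In the CD300c-iCre line it stood at 3.40 ± 0.416 CPM in pDC-like cells, and in the Ms4a3-Cre line 0 UMIs of it were counted in these classes. Which Cre sequence the Ms4a3-Cre construct carries is not given in the sources used here, so this 0 does not show that its driver was silent. A further Cre sequence in the reference had 0 UMIs in every class of the 3 lines. Il7r and Cd300c were each lower in the line that carried Cre there, where the mice were heterozygous for the construct. Whether the construct itself lowers these transcripts was not tested. In pDC-like cells Il7r stood at 372 ± 15.7 against 180.2 ± 8.54 CPM in the CD300c-iCre against the IL-7R-Cre line (log2 fold change 1.04, SE 0.05, adjusted p = 3.2e-06), and at 180.2 ± 8.54 against 319 ± 6.81 CPM in the IL-7R-Cre against the Ms4a3-Cre line (log2 fold change -0.82, SE 0.05, adjusted p = 2.3e-05). Cd300c stood at 272 ± 20.3 against 420.1 ± 17.1 CPM in the CD300c-iCre against the IL-7R-Cre line (log2 fold change -0.63, SE 0.07, adjusted p = 0.00316), with 413 ± 33.7 CPM in the Ms4a3-Cre line. Its neighbour Cd300c2 (chromosome 11, 114996721 to 115001880, minus strand) did not pass the test between any 2 lines in cDC2-, cDC1- or pDC-like cells. Ms4a3 was not among the genes tested in these classes, with 0 UMIs in cDC2-like cells of the 9 mice.

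tdTomato-positive and negative cDC2-like cells of the CD300c-iCre line differed in genes of the cDC2 subsets. Of 12691 genes, 1384 were higher and 1381 lower in positive cells (2765 in all, edgeR quasi-likelihood test with the mouse as block, Benjamini-Hochberg adjusted p at or under 0.05, n = 3 mice). The largest rise was in Bmp2, a secreted growth factor (29.7 ± 10.4 against 11.7 ± 2.82 CPM, log2 fold change 1.34, SE 0.13, adjusted p = 6.8e-09). Next came, with their log2 fold changes, the calcium sensor Ncald (1.12), the transcription factor Sox4 (1.10), the kinase Mast4 (1.09), the Polycomb protein Phc1 (1.06) and the scaffold Dlg2 (1.04). Slc16a6 (1.00), Serpinb6b (0.99), Sept1 (0.97) and the Notch pathway gene Dtx1 (119 ± 5.98 against 62.1 ± 4.22 CPM, log2 fold change 0.94, SE 0.06, adjusted p = 2.0e-12) followed. The largest falls were in the Ly49 receptor Klra2 (-2.87), the lipid regulator Pparg (-2.65), the complement genes C1qb (-2.43) and C1qa (-1.99) and the integrin Itga8 (-2.30). They were followed by angiotensin-converting enzyme Ace (-2.15), Ms4a7 (-2.06), Myof (-1.96), the inhibitory IgG receptor Fcgr2b (-2.05) and lysozyme, Lyz2 (260.1 ± 57.6 against 1136 ± 202 CPM, log2 fold change -2.13, SE 0.09, adjusted p = 7.0e-17).

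The fixed lists moved in the same way. The cDC2A, cDC2B and DC3 lists also served to name the cDC2 subclasses, whose tdTomato-positive shares differed in each line. Their movement, here and in the other lines, can follow from that difference and is no separate support for it. Among cDC2A genes 7 of 9 were higher and 1 lower over all genes, the same counts adjusted over the list alone (camera adjusted p = 0.00145, adjusted p = 0.0597 with an estimated correlation). They were led by the nuclear receptor Nr4a3 (740.2 ± 143 against 425 ± 61.4 CPM, log2 fold change 0.80, SE 0.04, adjusted p = 7.2e-15). The cDC2B list had 9 of 11 lower and 1 higher both ways (camera adjusted p = 8.9e-08, adjusted p = 0.0420 with an estimated correlation). The lectin Cd209a stood at 145 ± 16.8 against 322 ± 63.3 CPM (log2 fold change -1.14, SE 0.04, adjusted p = 2.8e-17), beside the ion channel gene Tmem176a (-0.85). The DC3 list, of genes shared with monocytes, had 9 of 13 lower and 1 higher both ways (camera adjusted p = 2.3e-06, adjusted p = 0.0641 with an estimated correlation). Among them were the lectin Clec4a3 (-1.77), the M-CSF receptor Csf1r (-1.52) and the fractalkine receptor Cx3cr1 (-1.46). Of 8 genes measured from the granulocyte-monocyte progenitor list, 7 were lower both ways (camera adjusted p = 3.3e-08, adjusted p = 0.0332 with an estimated correlation). These were Lyz2, Csf1r, Ccr2 and others that mature monocytes also express, and the granule proteases of progenitors were not measured. Lysosomal genes were 11 of 14 lower over all genes and 12 adjusted over the list alone (camera adjusted p = 4.6e-08, adjusted p = 0.0538 with an estimated correlation). Prosaposin, Psap, stood at 475 ± 14.8 against 1204 ± 51.0 CPM (log2 fold change -1.34, SE 0.03, adjusted p = 9.7e-23), beside the protease Lgmn (-0.84). Red pulp macrophage genes were 10 of 11 lower over all genes and 10 adjusted over the list alone (camera adjusted p = 2.1e-06, adjusted p = 0.0538 with an estimated correlation), with Spic (-1.59) and Axl (-2.26). Non-classical monocyte genes had 8 of 11 lower and 3 higher both ways (camera adjusted p = 0.00519, adjusted p = 0.0664 with an estimated correlation), with Adgre4 (-1.88). Pattern recognition receptors were 6 of 16 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00625, adjusted p = 0.162 with an estimated correlation), with Clec4a1 (-0.66) and Cd14 (-1.44). A positive call needed 1 UMI, so positive cells were deeper (medians 9455 to 9940 against 8905 to 9331 UMIs). With all cells thinned to 3000 UMIs 1195 genes passed. Within cDC2A-like cells alone 944 genes passed, with Cd14 at 0.72, Itga8 at 0.25 and Lgmn at 0.13. Within cDC2B/DC3-like cells alone 374 passed, with Mast4 at -0.12. With the subclasses thinned as well, Spic stood at 0.47, Lgmn at 0.27, Cd14 at 0.14, Ms4a7 at 0.019, Tmem176a at 5.2e-04 and Serpinb6b at -0.16 in cDC2A-like cells, and Mast4 at -0.22 in cDC2B/DC3-like cells.

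In the IL-7R-Cre line, positive cDC2-like cells leaned the same way, with fewer genes passing. Of 12691 genes, 566 were higher and 457 lower in positive cells (edgeR, n = 3 mice). Bmp2 rose again (29.8 ± 4.37 against 14.7 ± 0.521 CPM, log2 fold change 1.02, SE 0.11, adjusted p = 1.5e-07). So did Dlg2 (0.93), the nuclear receptor Esrrg (0.88), Phc1 (0.80), the B cell kinase Blk (0.79), Ncald (0.77), Dip2c (0.75), Eml5 (0.74), the calcium channel Ryr3 (0.73) and the actin bundler Fscn1 (0.73). Il7r itself was higher in positive cells at 6.82 ± 1.42 against 3.96 ± 0.948 CPM (log2 fold change 0.77, SE 0.16, adjusted p = 0.00205). Both levels were low beside that of pDC-like cells of the same line, and free RNA as their source was not tested. Ace was lower (15 ± 3.66 against 28.9 ± 1.55 CPM, log2 fold change -0.98, SE 0.10, adjusted p = 1.8e-07), followed by the leukotriene receptor Ltb4r1 (-0.84), the prostaglandin-degrading enzyme Hpgd (-0.82), Clec4a3 (-0.78), Abca9 (-0.77), metallothionein Mt1 (-0.76), Mcub (-0.73), Adgre4 (-0.72), Fcgr2b (-0.72) and the LPS co-receptor Cd14 (-0.71). The cDC2B list had 9 of 11 lower and 1 higher both ways (camera adjusted p = 7.7e-08, adjusted p = 0.0372 with an estimated correlation). Granulocyte-monocyte progenitor genes, again those shared with monocytes, were 6 of 8 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 7.7e-08, adjusted p = 0.0372 with an estimated correlation). cDC2A genes were 4 of 9 higher over all genes and 5 adjusted over the list alone (camera adjusted p = 9.7e-04, adjusted p = 0.0832 with an estimated correlation), with Dtx1 (0.54) and Nr4a3 (0.40). Of 10 MHC class II genes, 7 were lower and 1 higher over all genes, 7 and 2 adjusted over the list alone (camera adjusted p = 0.00841, adjusted p = 0.326 with an estimated correlation), with Cd74, the invariant chain, at -0.14. DC3 genes were 6 of 13 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 6.9e-05, adjusted p = 0.158 with an estimated correlation), with Csf1r (-0.57). Within cDC2A-like cells alone 212 genes passed in this line, and within cDC2B/DC3-like cells alone 12, with Esrrg at -1.08 and Ncald at -0.078. After thinning, Cd74 stood at 0.0022 in cDC2A-like cells, and Ltb4r1 at 0.10 and Mcub at 0.34 in cDC2B/DC3-like cells.

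Positive cDC2-like cells of the Ms4a3-Cre line showed the reverse pattern. Of 12691 genes, 528 were higher and 353 lower in positive cells (edgeR, n = 3 mice). Lyz2 rose from 455 ± 110.01 to 899 ± 172 CPM (log2 fold change 1.00, SE 0.09, adjusted p = 6.2e-09). The membrane repair gene Myof (1.12), Ace (0.99), the macrophage factor Spic (0.98), the lipid droplet gene Plin2 (0.97), the IgG receptor Fcgr4 (0.94), Pparg (0.94), the monocyte chemokine receptor Ccr2 (0.89), the chemokine Ccl6 (0.88) and the inhibitory receptor Lilrb4a (0.88) rose with it. Lower were Ccdc192 (-0.86), Serpinb6b (-0.66), Dlg2 (-0.63), the adaptor Nck2 (-0.60), Dtx1 (51.9 ± 3.16 against 79.0 ± 8.87 CPM, log2 fold change -0.60, SE 0.07, adjusted p = 7.5e-07) and Blk (-0.59). The haemoglobin genes Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt also passed (log2 fold changes of -3.80 to -3.46). Their level in negative cells had an SD above its mean (105 ± 149 CPM for Hbb-bs), since 1 mouse held most of it. Granulocyte-monocyte progenitor genes were 7 of 8 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 8.4e-10, adjusted p = 0.0208 with an estimated correlation). DC3 genes were 8 of 13 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 2.0e-08, adjusted p = 0.0364 with an estimated correlation), with Clec4a3 (0.79). Lysosomal genes were 10 of 14 higher over all genes and 11 adjusted over the list alone (camera adjusted p = 2.1e-09, adjusted p = 0.0364 with an estimated correlation), with Psap (0.57) and Lgmn (0.43). The cDC2B list had 7 of 11 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.0364 with an estimated correlation). cDC2A genes were 2 of 9 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 2.0e-04, adjusted p = 0.0364 with an estimated correlation), with Nr4a3 (-0.30). MHC class I genes such as H2-D1 (0.14) and H2-K1 (0.13) were 3 of 11 higher over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00885, adjusted p = 0.191 with an estimated correlation). MHC class II genes such as Cd74 (0.15) and H2-Eb1 (0.16) were 6 of 10 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0177, adjusted p = 0.322 with an estimated correlation). In the unthinned calls compared here 26% ± 0.618 of the cells were positive, against 16.5% ± 2.78 of the shallower T cell-like cells. Within cDC2A-like cells alone 7 genes passed, with Fcgr4 at -0.092, and within cDC2B/DC3-like cells alone 1, with Cd74 at -0.0056, H2-D1 at -0.012, Hba-a1 at 0.47 and Hba-a2 at 0.56. With these thinned as well, Spic stood at -0.40, Ccdc192 at 0.55 and Hba-a1 at 0.50.

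**Figure D3:**
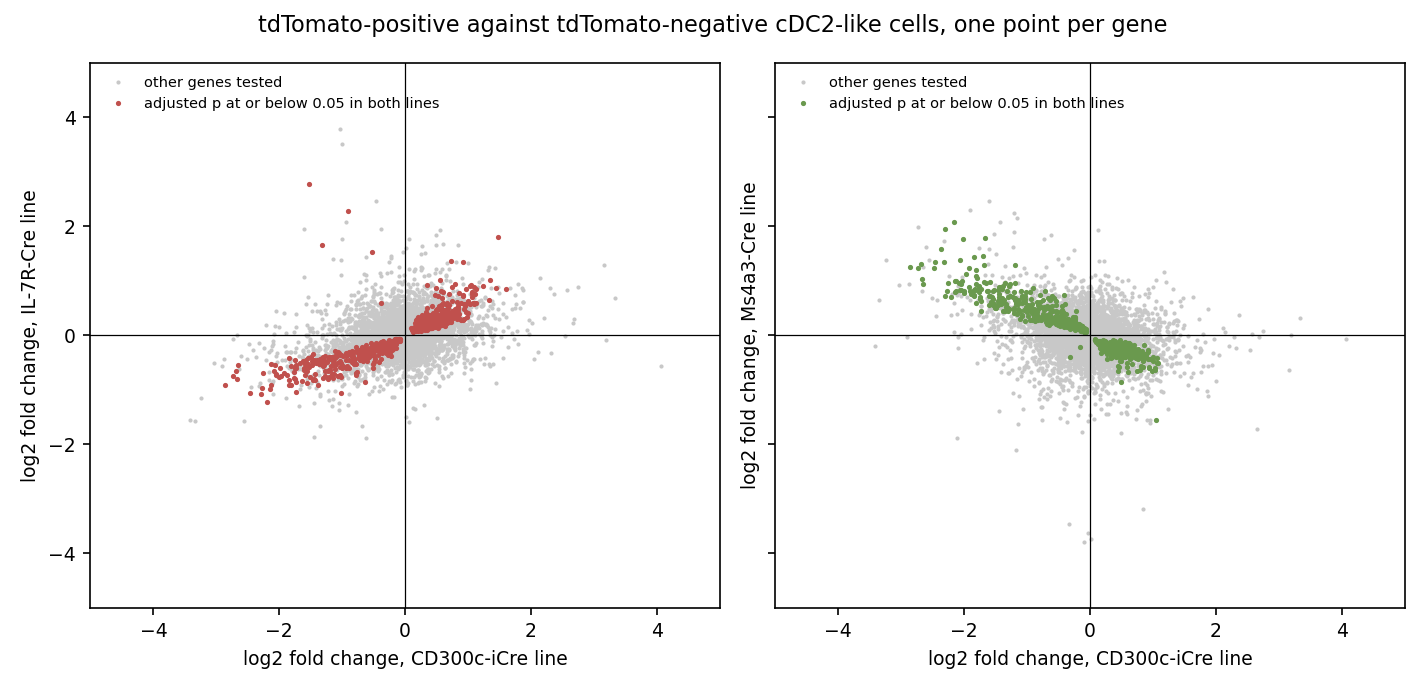
Log2 fold change between tdTomato-positive and negative cDC2-like cells, with 1 point per gene tested. The horizontal axis is the CD300c-iCre line, and the vertical axis is the IL-7R-Cre line (left) or the Ms4a3-Cre line (right). Coloured points had an adjusted p (edgeR) at or under 0.05 in both lines of the panel. Lyz2 stands at -2.13 in the CD300c-iCre line and at 1.00 in the Ms4a3-Cre line, and Dtx1 at 0.94 and -0.60.

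The differences were themselves tested between lines. The gap between positive and negative cDC2-like cells differed for 673 genes between the CD300c-iCre and IL-7R-Cre lines (252 higher, 421 lower). It differed for 2786 between the CD300c-iCre and Ms4a3-Cre lines (1369 and 1417) and for 1687 between the IL-7R-Cre and Ms4a3-Cre lines (850 and 837; edgeR, n = 3 mice per line). With all cells thinned to 3000 UMIs the 3 counts were 49, 1283 and 1114, of which 41, 1197 and 947 genes were among those above. Within cDC2A-like cells alone they were 155, 382 and 108, and within cDC2B/DC3-like cells alone 63, 347 and 25. Without the mouse as block they were 39, 1120 and 254. Between the CD300c-iCre and Ms4a3-Cre lines the gap differed most by -3.14 on the log2 scale for Ace, by -3.13 for Lyz2 (SE 0.12, adjusted p = 2.9e-17), -3.08 for C1qb, -2.89 for Ms4a7 and -2.88 for Fcgr2b. The other way, apart from the haemoglobin genes, it differed by 1.68 for Dlg2, 1.60 for Mast4 and 1.54 for Dtx1 (SE 0.09, adjusted p = 2.6e-13). Between the CD300c-iCre and IL-7R-Cre lines it was -2.16 for C1qb, -1.60 for Lyz2 and -1.53 for Ms4a7. It was 0.76 for the calcium channel gene Cacna1e, 0.62 for Irf4, a transcription factor of cDC2, and 0.62 for the interleukin 1 decoy receptor Il1r2. Some values changed sign within a subclass. None of these passed the threshold for the genes named in this paragraph. For other genes, such as Il1b, Cd74, Nfkbia and Crip1, some passed in the opposite direction. Between the CD300c-iCre and IL-7R-Cre lines Ms4a7 stood at 0.039 in cDC2A-like cells, and after thinning Ms4a7 stood at 0.11 and Lyz2 at 0.34 there and Irf4 at -0.32 in cDC2B/DC3-like cells. Between the CD300c-iCre and Ms4a3-Cre lines Mast4 stood at -0.091 in cDC2B/DC3-like cells. Between the IL-7R-Cre and Ms4a3-Cre lines Ace (-1.98), Clec4a3 (-1.57), Dlg2 (1.57) and Blk (1.38) led. Of the genes called in the CD300c-iCre line, 885 were also called in the IL-7R-Cre line, 880 in the same direction (independent lists would share 223). In the Ms4a3-Cre line 733 were called too, 731 in opposite directions (192). The IL-7R-Cre and Ms4a3-Cre lines shared 495 genes, all in opposite directions (71.0). tdTomato marked cDC2A-like cells more often than cDC2B/DC3-like cells in the CD300c-iCre and IL-7R-Cre lines and less often in the Ms4a3-Cre line. These overlaps can follow from that difference in subclass mix. Within a single subclass, few genes passed in the Ms4a3-Cre line, as given above.

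cDC1-like cells were compared in the same way, but at 1 UMI after thinning their positive shares were not far from the background. Thinned, they were 22.0%, 17.4% and 9.34% in the CD300c-iCre, IL-7R-Cre and Ms4a3-Cre lines against backgrounds of 15.2%, 12.8% and 9.59%. At 1 UMI without thinning, the call used here, 54.7%, 47.5% and 31.4% of these deep cells were positive. The shallower background classes then stood at 28.0%, 21.4% and 16.5%. At 2 or more UMIs after thinning, 7.30% ± 0.855 of cDC1-like cells were positive in the CD300c-iCre line against 1.59% ± 0.462 of T cell-like cells, and 4.25% ± 1.62 in the IL-7R-Cre line against 0.826% ± 1.43 of non-classical monocyte-like cells. In the Ms4a3-Cre line it was 1.44% ± 0.587 against 0.566% ± 0.507 of T cell-like cells. Their tdTomato level was 110.2 ± 6.92, 80.8 ± 9.80 and 37.1 ± 3.75 CPM against 43.3, 37.5 and 32.8 CPM in these background classes. Many calls at 1 UMI can therefore be free RNA, and small counts of genes do not show that labelled cDC1-like cells differ little. Of 11469 genes, 14 passed in the CD300c-iCre line (9 higher, 5 lower in positive cells), 41 in the IL-7R-Cre line (15 and 26) and 4 in the Ms4a3-Cre line (2 and 2). By edgeR 706, 1042 and 775 had an unadjusted p under 0.05. The ubiquitin ligase gene Rnf217 was higher in positive cells of the CD300c-iCre line (27.8 ± 3.60 against 19.7 ± 4.97 CPM, log2 fold change 0.52, SE 0.11, adjusted p = 0.0415) and of the Ms4a3-Cre line (log2 fold change 0.78, SE 0.14, adjusted p = 0.00339). It was lower in the IL-7R-Cre line (log2 fold change -0.55, SE 0.12, adjusted p = 0.0236). In the CD300c-iCre line the kinase Ptk2b (0.25), the early response genes Jun (0.23), Zfp36 (0.18), Btg2 (0.15) and Fos (0.13), the chaperone Hspa5 (0.15) and Rgs2 (0.18) were higher and the interferon-induced Ifi27l2a (-0.38) lower. Immediate early and heat shock genes there were 2 of 14 higher over all genes and 10 adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.248 with an estimated correlation). In the IL-7R-Cre line the cDC1 marker Cd8a (280.1 ± 8.96 against 239.8 ± 10.1 CPM, log2 fold change 0.22, SE 0.04, adjusted p = 7.7e-04) was higher. So were the endoplasmic reticulum chaperones Manf (0.27), Calr (0.17), Sdf2l1 (0.21), P4hb (0.18) and Hsp90b1 (0.15), Nucb2 (0.27), Cdk11b (0.20), Arhgap42 (0.37) and the sterol enzyme Fdps (0.27). Lower there were Zdhhc14 (-0.45), the pyrin gene Mefv (-0.32), Rgs1 (-0.28), Hivep2 (-0.27), Nr4a3 (-0.26), Klri1 (-0.25), Zfp148 (-0.23), Wipf1 (-0.21) and Malt1 (-0.18). In the Ms4a3-Cre line Sdf2l1 (0.28) was higher and the T cell adaptor gene Grap2 (-0.47) lower. Named after their values were seen, the others lower in the CD300c-iCre line were Gm26917 (-0.46), Cpne8 (-0.60), Slc40a1 (-1.65) and Fhit (-0.60), and in the Ms4a3-Cre line Gm42418 (-0.21). The gap between positive and negative cells differed between the CD300c-iCre and Ms4a3-Cre lines for Zdhhc14 (0.62), Ptk2b (0.39) and the NF-kB subunit gene Rel (0.26), with adjusted p = 0.0269 for each by edgeR. With DESeq2's Wald test 0 genes passed in the CD300c-iCre and Ms4a3-Cre lines (119 and 176 at an unadjusted p under 0.05). Positive cells were deeper, with medians of 18756 to 20053 against 16409 to 18564 UMIs in the IL-7R-Cre line. With cells thinned to 3000 UMIs, 17, 1 and 0 genes passed in the 3 lines by edgeR (498, 396 and 543 unadjusted), of which 3, 1 and 0 were among those above. cDC1-like cells of the 3 lines lay in different clusters. Cluster 3 held 1752, 1328 and 362 and cluster 14 held 4, 7 and 1160 of the CD300c-iCre, IL-7R-Cre and Ms4a3-Cre cells. Without them Rnf217 stood at -0.089 in the CD300c-iCre line and Arhgap42 at -0.44 in the IL-7R-Cre line. After thinning, Wipf1 stood at 0.045 in the IL-7R-Cre line, and the difference for Ptk2b between the CD300c-iCre and Ms4a3-Cre lines at -0.011.

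Between whole lines, most genes passed in cDC2-like cells for the CD300c-iCre against the Ms4a3-Cre line. There were 710 genes higher and 826 lower in the CD300c-iCre line of 13315 tested (edgeR, n = 3 mice per line). Beside tdTomato (2.90), the interferon-induced Isg15 stood at 102 ± 9.31 against 38.2 ± 4.69 CPM (log2 fold change 1.41, SE 0.12, adjusted p = 1.2e-04). Also higher were Ryr3 (0.96), the early response gene Jun (0.75), the peptidoglycan receptor Pglyrp1 (0.73), Unc119 (0.72), Rgs3 (0.70), Eps8 (0.69), the enolase Eno3 (0.68) and creatine kinase Ckb (0.67). Lower was Hebp1, a haem-binding protein gene (chromosome 6, 135137522 to 135198022, minus strand), at 7.86 ± 0.157 against 78.1 ± 8.13 CPM (log2 fold change -3.31, SE 0.11, adjusted p = 1.8e-07). Also lower were the Ly49 receptor Klra17 (-2.36), Insyn2b (-1.75), the NF-kB regulator Tnip3 (-1.72), Cd300c (-1.59), Cacnb2 (-1.46), the mitochondrial tRNA synthetase Lars2 (-1.45), the Mediator kinase Cdk8 (-1.43), Cmss1 (-1.34) and mt-Atp8 (-1.28). Glycolysis genes were 6 of 13 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 5.1e-04, adjusted p = 0.236 with an estimated correlation), with Ldha (0.45) and Eno1 (0.41). Immediate early and heat shock genes were 4 of 14 higher over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.608 with an estimated correlation), with Junb (0.31). Transitional DC genes were 5 of 11 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 0.00189, adjusted p = 0.332 with an estimated correlation), with the growth factor receptor Flt3 (-0.38) and Lifr (-0.95). Gm42418 and AY036118, which can collect reads of ribosomal RNA, moved with the line as well and are named after their values were seen. In cDC2-like cells the log2 fold change was -0.93 (SE 0.04, adjusted p = 3.7e-07) for Gm42418 and -1.30 (SE 0.06, adjusted p = 1.6e-06) for AY036118, at 241 against 596 CPM, and in cDC1- and pDC-like cells they were lower in the CD300c-iCre line too. Markers of other cell types moved with the line. NK cell genes, none of which another list holds, were 9 of 12 lower over all genes and 10 adjusted over the list alone (camera adjusted p = 2.4e-10, adjusted p = 0.0279 with an estimated correlation), with Nkg7 at 1.77 ± 0.0459 against 11.6 ± 1.06 CPM. T cell genes were 8 of 12 lower over all genes and 10 adjusted over the list alone (camera adjusted p = 5.1e-06, adjusted p = 0.0279 with an estimated correlation), with Cd3g at 0.493 ± 0.0578 against 2.15 ± 0.322 CPM. NK and T cell-like cells were 9.86% and 6.68% of that line against 2.60% and 3.05% of the CD300c-iCre line.

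Fewer genes passed between the IL-7R-Cre line and either of the other lines. Against the Ms4a3-Cre line 53 genes were higher and 111 lower in its cDC2-like cells. Higher were Isg15 (76.2 ± 9.99 against 38.2 ± 4.69 CPM, log2 fold change 1.00, SE 0.12, adjusted p = 0.00506), the stress genes Atf3 (0.62) and Egr1 (0.58), the lysosomal transporter Slc15a3 (0.61), Hpgd (0.59), the cytokine subunit Ebi3 (0.44), Cmtm7 (0.52) and Apobr (0.47). Lower were Hebp1 (6.77 ± 0.946 against 78.1 ± 8.13 CPM, log2 fold change -3.54, SE 0.11, adjusted p = 3.9e-07), Insyn2b (-1.15), Lrrc4 (-0.82), Lars2 (-0.78), Cdk8 (-0.72), Gphn (-0.62) and its own driver, Il7r (5.44 ± 0.913 against 12.3 ± 0.921 CPM, log2 fold change -1.19, SE 0.14, adjusted p = 0.00520). Immediate early and heat shock genes were 3 of 14 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 7.2e-06, adjusted p = 0.336 with an estimated correlation). MHC class II genes were 1 of 10 higher over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00457, adjusted p = 0.474 with an estimated correlation), with Cd74 (0.33). NK cell genes were 4 of 12 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 4.0e-07, adjusted p = 0.0695 with an estimated correlation). Between the CD300c-iCre and IL-7R-Cre lines 16 genes were higher and 65 lower. Higher were the chemokine receptor Ccr6 (0.54), the lectin Cd22 (0.48), Alyref (0.41), properdin Cfp (0.40), profilin Pfn1 (0.39) and Cd7 (0.32). Lower were Kazn (-0.95), the chemokine Ccl9 (-0.95), Cmss1 (-0.88), the immunoglobulin genes Igha (-0.81) and Iglc1 (-0.63), mt-Atp8 (-0.77), Cdk8 (-0.71), Lars2 (-0.67), Pdcd4 (-0.65) and the repressor Bach2 (-0.55). Cd300c stood at 6.65 ± 1.21 against 17.5 ± 1.92 CPM (log2 fold change -1.38, SE 0.13, adjusted p = 0.00113). By DESeq2's Wald test 264 genes passed between these lines and 334 between the IL-7R-Cre and Ms4a3-Cre lines. NK cell genes were 5 of 12 lower over all genes and 8 adjusted over the list alone (camera adjusted p = 2.3e-12, adjusted p = 0.0353 with an estimated correlation). cDC2B genes were 0 of 11 lower over all genes and 8 adjusted over the list alone (camera adjusted p = 6.5e-04, adjusted p = 0.335 with an estimated correlation), with Clec12a (-0.63, adjusted p = 0.0897) and Ccr2 (-0.76, adjusted p = 0.112) in front. The subclass mix differed too. cDC2B/DC3-like cells were 744 of 3125, 593 of 2449 and 506 of 1977 cDC2-like cells in the CD300c-iCre mice. In the IL-7R-Cre mice they were 683 of 2620, 630 of 1622 and 812 of 2348. Whether this mix lowered the list was not tested.

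Many of the genes that differed between lines in cDC2-like cells did so in cDC1- and pDC-like cells as well. In cDC1-like cells 573 genes were higher and 688 lower in the CD300c-iCre than in the Ms4a3-Cre line of 12176 tested. The counts were 42 and 84 in the IL-7R-Cre than in the Ms4a3-Cre line, and 4 and 28 in the CD300c-iCre than in the IL-7R-Cre line. The 4 were human CD2, Iglc2 (1.16), Ppp4c (0.30) and Pfn1 (0.26), named after their values were seen. The invariant chain Cd74 was at 18821 ± 382 against 14560.0 ± 384 CPM in the CD300c-iCre against the Ms4a3-Cre line (log2 fold change 0.37, SE 0.04, adjusted p = 2.0e-04). MHC class II genes were 3 of 10 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00544, adjusted p = 0.484 with an estimated correlation). Csrnp1 (0.73), the stress gene Gadd45b (0.72), Alyref (0.65) and Marcksl1 (0.57) were higher. Lower were Insyn2b (-1.80), thyroglobulin Tg (-1.54), the lectin Clec1a (-1.35), the opioid receptor Oprm1 (-1.19) and Lars2 (-1.39). Glycolysis genes were 8 of 13 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 1.6e-05, adjusted p = 0.0656 with an estimated correlation), with Ldha (0.44) and Pkm (0.38). NK cell genes were 9 of 11 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 2.2e-09, adjusted p = 0.0933 with an estimated correlation). In pDC-like cells the counts were 473 and 543 of 12163, 39 and 100, and 6 and 40 in the same order of lines. The interferon-induced Isg15 (1.31), Jund (0.70), Cmtm7 (0.69) and the proton pump gene Atp6ap1 (0.59) were higher in the CD300c-iCre than in the Ms4a3-Cre line. Lower were Insyn2b (-2.09), the chemokine Ccl5 (32.9 ± 3.21 against 110.3 ± 5.29 CPM, log2 fold change -1.74, SE 0.08, adjusted p = 3.1e-07), Clec1a (-1.64), Lrrc4 (-1.45) and Cdk8 (-1.30). Lysosomal genes were 5 of 14 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 4.0e-04, adjusted p = 0.246 with an estimated correlation), with Psap (0.29) and Grn (0.28). NK cell genes were 9 of 11 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 2.7e-09, adjusted p = 0.127 with an estimated correlation). Between the CD300c-iCre and Ms4a3-Cre lines 313 genes were higher and 395 lower in both cDC2- and cDC1-like cells, where independent lists would share 33.3 and 42. There were 235 and 315 in both cDC2- and pDC-like cells (27.5 and 31.8). The same mice and libraries enter each class, so line and library cannot be told apart here. Without clusters 3 and 14, 2720 genes passed in cDC1-like cells between these lines.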

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

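The tests of explanations, the splits of the mice and the tests within single cDC2 subclasses in this part were chosen after the results were seen, while the other tests of differences between lines were planned. tdTomato marked cDC2A-like more often than cDC2B/DC3-like cells in the CD300c-iCre and IL-7R-Cre lines and less often in the Ms4a3-Cre line, a difference between groups (exact permutation p = 0.00357). In cDC2-like cells the gap between positive and negative cells differed for 673 genes between the CD300c-iCre and IL-7R-Cre lines, for 2786 between the CD300c-iCre and Ms4a3-Cre lines and for 1687 between the IL-7R-Cre and Ms4a3-Cre lines. With cells thinned to 1 depth these counts were 49, 1283 and 1114, in cDC2A-like cells alone 155, 382 and 108 and in cDC2B/DC3-like cells alone 63, 347 and 25. In cDC1-like cells they were 36, 3 and 8 (6, 3 and 0 thinned, of which 4, 0 and 0 were among those genes, with 449 at an unadjusted p under 0.05 by edgeR where 0 passed).

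The tdTomato share of pDC-like cells in the Ms4a3-Cre line (25.7%) was low but above that of T cell-like cells. Free RNA alone is argued against, since in the 3 mice the share was 2.39 to 3.33 times that of T cell-like cells. Doublets with or RNA of labelled non-classical monocytes are argued against as well, since the median excess of 12 monocyte markers in pDC-like over T cell-like cells was -0.204% of the monocyte level, where the tdTomato would need 20.3%. A labelled minority with the tdTomato level of the CD300c-iCre line is argued against, since 3.34% (SD 0.772) of the cells held at least 4 tdTomato UMIs where 8.48% would be needed, a test that replaced an earlier one. A low level of tdTomato in many cells, with or without Cre in their progenitors, stays open and was not tested.

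Genes higher in the Ms4a3-Cre than in the CD300c-iCre line in cDC2-, cDC1- and pDC-like cells numbered 230, where independent lists would share 1.69. Free RNA of NK and T cells as the source of all of them is argued against, since for 200 of the 230 it gave under 25% of the rise in each class, while for 46 genes that NK or T cells hold at least 10 times above these classes it gave 50% or more for 24, so for these it stays open. Of the 230, 82 were antisense genes (35.7%, against 3.68% of the genes tested). The median log2 fold change over all tested antisense genes was -0.52 to -0.45 in the 3 classes, as more reads from the opposite strand in that library would give. It was -0.27 to -0.25 for the CD300c-iCre against the IL-7R-Cre line, and -0.28 to -0.25 for the IL-7R-Cre against the Ms4a3-Cre line. The shift therefore ran over the 3 libraries and was not in the Ms4a3-Cre library alone. Across genes, which are no independent replicates, the fold changes of cDC2- and pDC-like cells correlated at 0.695 (Pearson), as either library or line would give, and these cannot be told apart because each line is 1 library. The line itself stays open and untested.

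The mice of a line also differed from each other along an axis shared by the lines, which held 62.0% of the variance within lines over 4364 genes. In each line the mouse with the highest score also had the highest pDC-like share (28.7%, 34.6% and 19.9%). A shift in the mix between 4 kinds of cells (cDC2A-, cDC2B/DC3-, cDC1- and pDC-like) is argued against as the whole cause. In each kind taken alone, 9 of 9 mice lay on the same side. Each kind pools clusters, and a shift in their mix within a kind was not tested and stays open. The hashtag antibody is argued against by the deviations of same-numbered mice (correlations of -0.451 to 0.318). These were above 0.1 in the same 3 of 9 pairs in each of cDC2-, cDC1- and pDC-like cells. Time or temperature before capture stays open, since 10 of 14 immediate early and heat shock genes kept 1 sign in the 4 kinds of cells, 8 at the high and 2 at the low end. The design gives no biological explanation within a line, and none was tested.

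Chance differences between mice are argued against for the comparisons of the 3 lines. Of 100 splits of the mice drawn (of 280 possible), 1 gave as many genes, the real one. It gave 903 genes in cDC2-like cells against at most 534 in other splits, 703 against 304 in cDC1-like and 606 against 289 in pDC-like cells. The mice of a line share 1 library, so a chance difference between libraries was not tested. For 2 lines there are 10 splits, too few for a share under 0.05, and other splits gave at most 0 genes in cDC2- and pDC-like cells and at most 1 in cDC1-like cells, against 32 to 1536 in the real ones. For positive against negative cells there are 4 exchanges within the mice, also too few, with real counts of 2765, 1023 and 881 and highest others of 0, 0 and 1 in cDC2-like cells, and 14, 41 and 4 with 1, 0 and 5 in cDC1-like cells of the 3 lines. The differences between lines have 10 splits, too few again, with highest others of 0 in cDC2-like cells and of 2, 5 and 4 in cDC1-like cells.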

How the results depend on the processing

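Tests chosen after the data were seen are those that leave out clusters, take cDC2 subclasses alone, or ask for 2 or 4 tdTomato UMIs without thinning, and, for the gap between cDC2 subclasses, the other hashtag, doublet and cell filters and clustering without centring. The tdTomato share differed between the lines in 9 or 10 classes under each alternative and without any 1 mouse, and the gap between cDC2A-like and cDC2B/DC3-like cells kept its sign and an exact p of 0.00357 in all of them. It was 26.1 to 38.8 percentage points in the CD300c-iCre line, 13.7 to 21.5 in the IL-7R-Cre line and -17.7 to -8.33 in the Ms4a3-Cre line (without 1 mouse 32.1 to 35.9, 18.6 to 19.9 and -13.6 to -11.8). The T cell-like share, the 1 class share that passed, no longer passed (0 classes) with the dominant hashtag, with Scrublet-marked cells kept, under the stricter cell filter and without any 1 mouse of the CD300c-iCre or IL-7R-Cre line (0 to 1 classes), and the cause was not tested. Depth limits the shares of classes with few labelled cells, since a thinned cell holds 3000 UMIs.

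For counts of genes past the threshold, each follows as the count in the report and the range without 1 mouse, with each mouse whose absence moved it by over 1.5 times. For cDC2-like cells, the 3 lines gave 903 (336 to 1010, leaving out CD300c-iCre mice 1, 2 and 3 gave 441, 336 and 509, IL-7R-Cre mouse 3 gave 556, Ms4a3-Cre mice 2 and 3 gave 368 and 480). CD300c-iCre against IL-7R-Cre gave 81 (15 to 119, leaving out CD300c-iCre mice 1, 2 and 3 gave 15, 20 and 20, IL-7R-Cre mice 1, 2 and 3 gave 35, 29 and 19, Ms4a3-Cre mice 2 and 3 gave 30 and 51). CD300c-iCre against Ms4a3-Cre gave 1536 (676 to 1739, leaving out CD300c-iCre mice 1, 2 and 3 gave 865, 676 and 948, Ms4a3-Cre mice 2 and 3 gave 723 and 953). IL-7R-Cre against Ms4a3-Cre gave 164 (29 to 106, leaving out CD300c-iCre mice 1, 2 and 3 gave 80, 71 and 106, IL-7R-Cre mice 1, 2 and 3 gave 54, 51 and 29, Ms4a3-Cre mice 1, 2 and 3 gave 89, 46 and 58). For cDC1-like cells, the 3 lines gave 703 (259 to 770, leaving out CD300c-iCre mice 1, 2 and 3 gave 407, 259 and 426, IL-7R-Cre mouse 3 gave 461, Ms4a3-Cre mice 2 and 3 gave 300 and 295). CD300c-iCre against IL-7R-Cre gave 32 (12 to 68, leaving out CD300c-iCre mice 1, 2 and 3 gave 12, 13 and 17, IL-7R-Cre mice 1, 2 and 3 gave 12, 16 and 17, Ms4a3-Cre mouse 1 gave 68). CD300c-iCre against Ms4a3-Cre gave 1261 (508 to 1329, leaving out CD300c-iCre mice 1 and 2 gave 780 and 508, Ms4a3-Cre mice 2 and 3 gave 687 and 668). IL-7R-Cre against Ms4a3-Cre gave 126 (25 to 110, leaving out CD300c-iCre mouse 2 gave 69, IL-7R-Cre mice 1, 2 and 3 gave 32, 60 and 25, Ms4a3-Cre mice 2 and 3 gave 34 and 28). For pDC-like cells, the 3 lines gave 606 (239 to 556, leaving out CD300c-iCre mice 1, 2 and 3 gave 349, 288 and 395, Ms4a3-Cre mice 2 and 3 gave 239 and 379). CD300c-iCre against IL-7R-Cre gave 46 (22 to 63, leaving out CD300c-iCre mice 1, 2 and 3 gave 29, 27 and 27, IL-7R-Cre mouse 1 gave 22). CD300c-iCre against Ms4a3-Cre gave 1016 (477 to 1014, leaving out CD300c-iCre mice 1, 2 and 3 gave 592, 527 and 618, Ms4a3-Cre mouse 2 gave 477). IL-7R-Cre against Ms4a3-Cre gave 139 (30 to 143, leaving out CD300c-iCre mouse 2 gave 77, IL-7R-Cre mice 1, 2 and 3 gave 30, 57 and 34, Ms4a3-Cre mice 1, 2 and 3 gave 82, 42 and 73). For positive against negative cDC2-like cells, CD300c-iCre gave 2765 (2040 to 2871). CD300c-iCre against IL-7R-Cre gave 673 (466 to 726). CD300c-iCre against Ms4a3-Cre gave 2786 (2270 to 2796). IL-7R-Cre gave 1023 (550 to 1065, leaving out IL-7R-Cre mice 1, 2 and 3 gave 603, 655 and 550). IL-7R-Cre against Ms4a3-Cre gave 1687 (1201 to 1740). Ms4a3-Cre gave 881 (393 to 916, leaving out Ms4a3-Cre mice 2 and 3 gave 525 and 393). For positive against negative cDC1-like cells, CD300c-iCre gave 14 (3 to 27, leaving out CD300c-iCre mice 2 and 3 gave 3 and 4, Ms4a3-Cre mouse 2 gave 27). CD300c-iCre against IL-7R-Cre gave 36 (15 to 55, leaving out CD300c-iCre mouse 3 gave 15, IL-7R-Cre mice 1 and 2 gave 22 and 20, Ms4a3-Cre mouse 2 gave 55). CD300c-iCre against Ms4a3-Cre gave 3 (0 to 16, leaving out CD300c-iCre mouse 2 gave 1, Ms4a3-Cre mice 1 and 2 gave 0 and 16). IL-7R-Cre gave 41 (6 to 73, leaving out IL-7R-Cre mice 1, 2 and 3 gave 6, 17 and 24, Ms4a3-Cre mouse 2 gave 73). IL-7R-Cre against Ms4a3-Cre gave 8 (2 to 9, leaving out CD300c-iCre mouse 3 gave 5, IL-7R-Cre mice 1, 2 and 3 gave 2, 2 and 5, Ms4a3-Cre mice 1 and 3 gave 3 and 4). Ms4a3-Cre gave 4 (3 to 9, leaving out Ms4a3-Cre mouse 2 gave 9). The 0 genes without Ms4a3-Cre mouse 1 are by edgeR, with 727 at an unadjusted p under 0.05. Fewer samples lower such counts, and why single mice raised some was not tested.

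Same-numbered mice of different lines did not deviate together, so the numbers do not pair the mice. The correlations were -0.451 to 0.318, and over 0.1 in the same 3 of 9 pairs in each of cDC2-, cDC1- and pDC-like cells. With the hashtag number as a replicate block, the counts for the 3 lines, CD300c-iCre against IL-7R-Cre, CD300c-iCre against Ms4a3-Cre and IL-7R-Cre against Ms4a3-Cre were 347, 18, 769 and 42 in cDC2-like, 268, 15, 651 and 31 in cDC1-like and 244, 26, 522 and 30 in pDC-like cells. Without the replicate block of the mouse, positive and negative cDC2-like cells differed in 1096, 25 and 6 genes in the CD300c-iCre, IL-7R-Cre and Ms4a3-Cre lines, with differences of 39, 1120 and 254 between lines, and cDC1-like cells in 0 in the 6 comparisons by edgeR (209 to 353 at an unadjusted p under 0.05; DESeq2 with the block called 0 to 41).

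In the order CD300c-iCre, IL-7R-Cre, Ms4a3-Cre, then CD300c-iCre against IL-7R-Cre, CD300c-iCre against Ms4a3-Cre and IL-7R-Cre against Ms4a3-Cre, the counts for positive against negative cDC2-like cells were 1698, 467, 482, 324, 1725 and 926 with DESeq2's Wald test, 944, 212, 7, 155, 382 and 108 in cDC2A-like and 374, 12, 1, 63, 347 and 25 in cDC2B/DC3-like cells alone, and 338, 225, 10, 32, 81 and 79 and 244, 8, 8, 63, 182 and 13 in these after thinning. Thinning all cells gave 1195 and 471 in the CD300c-iCre and Ms4a3-Cre lines and 49, 1283 and 1114 for the differences. With at least 2 UMIs for a positive cell the counts were 1705 and 1899 in the IL-7R-Cre and Ms4a3-Cre lines, 345 between the CD300c-iCre and IL-7R-Cre lines and 2770 between the IL-7R-Cre and Ms4a3-Cre lines, and without cluster 1 they were 1775 and 319 in the CD300c-iCre and IL-7R-Cre lines and 346, 1790 and 931 for the differences. For cDC1-like cells the 6 counts were 66, 78, 28, 75, 47 and 18 without a gene filter. DESeq2 called 0 and 0 in the CD300c-iCre and Ms4a3-Cre lines (119 and 176 unadjusted) and 10, 0 (149 unadjusted) and 1 for the differences, and its size factors in edgeR gave 5 between the IL-7R-Cre and Ms4a3-Cre lines. At 2 UMIs there were 40, 21 and 9 in the lines, with 6 and 13 for the differences from the Ms4a3-Cre line. Thinned cells gave 1 and 0 in the IL-7R-Cre and Ms4a3-Cre lines and 6 and 0 for the differences of the IL-7R-Cre line from the CD300c-iCre and Ms4a3-Cre lines (543 and 449 unadjusted where 0 passed). Without clusters 3 and 14 there were 88 and 130 in the IL-7R-Cre and Ms4a3-Cre lines and 9, 8 and 4 for the differences. Thinning and subclasses leave fewer counts and cells, but also change which cells are compared, and the cause was not tested.

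Between lines, without a gene filter, cDC1-like cells gave 1103 (3 lines), 171 (CD300c-iCre against IL-7R-Cre) and 229 (IL-7R-Cre against Ms4a3-Cre) and pDC-like cells 933, 112 and 275. DESeq2's Wald test gave 264 and 334 for these 2 pairs of lines in cDC2-like, 114 and 220 in cDC1-like and 81 and 218 in pDC-like cells. Equal cell numbers gave 463 (3 lines) and 72 (IL-7R-Cre against Ms4a3-Cre) in cDC1-like cells, and leaving out clusters 3 and 14 gave 1961 (3 lines), 2720 (CD300c-iCre against Ms4a3-Cre) and 859 (IL-7R-Cre against Ms4a3-Cre). cDC2A-like cells alone gave 38 and 94 for the CD300c-iCre against the IL-7R-Cre and the IL-7R-Cre against the Ms4a3-Cre line, and cDC2B/DC3-like cells alone 304, 19, 539 and 49 for the 3 lines and the 3 pairs. Subclasses and equal numbers leave fewer cells, and the cause was not tested otherwise.

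Of 139 list calls by camera, 28 held with an estimated correlation and 102 with fry, and 0 changed sign. With an estimated correlation, 1, 2 and 0 lists passed in cDC2-like cells (CD300c-iCre against IL-7R-Cre, CD300c-iCre against Ms4a3-Cre, IL-7R-Cre against Ms4a3-Cre), 0 in cDC1- and pDC-like cells, 2, 2 and 5 for positive against negative cDC2-like cells of the CD300c-iCre, IL-7R-Cre and Ms4a3-Cre lines, 5, 6 and 5 for their differences, and 0 for cDC1-like cells. With fry, the counts that moved were 4 in cDC2-like cells (IL-7R-Cre against Ms4a3-Cre), 10 and 5 in cDC1-like cells and 2 and 10 in pDC-like cells, 20 in positive against negative cDC2-like cells of the CD300c-iCre line and 22 for its difference from the Ms4a3-Cre line, and 0, 1 and 0 in cDC1-like cells of the CD300c-iCre, IL-7R-Cre and Ms4a3-Cre lines with 0 and 1 for the differences from the Ms4a3-Cre line.

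Over 8302 values of 483 named genes under the alternatives, 6584 kept direction and side of the threshold, 1599 fell below it and 119 changed sign, 111 of these under alternatives added after the data were seen. Of the 119, 29 passed the threshold in the opposite direction, and these have their adjusted p (edgeR) in parentheses. Over each gene the naming rule takes, 393 of 17742 values changed sign. The log2 fold changes with a changed sign follow, for positive against negative cDC2-like cells unless another comparison is named. In cDC2A-like cells alone, for CD300c-iCre Bcl11a -0.18 (0.0219), Cd14 0.72, Cd300c2 0.025, Cd74 0.13 (0.00128), H2-Ab1 0.15 (5.2e-04), H2-D1 0.12 (0.0266), H2-Eb1 0.18 (1.9e-05), Il1b 0.18 (0.00194), Itga8 0.25, Lgmn 0.13, Nfkbia 0.017; for CD300c-iCre against IL-7R-Cre Cd74 0.16 (0.032), H2-Ab1 0.18 (0.0151), Il1b 0.43 (3.5e-06), Ms4a7 0.039, Tmem176a 0.11; for CD300c-iCre against Ms4a3-Cre Cd300c2 0.021, H2-Eb1 0.16 (0.0191), Il1b 0.19 (0.0436); for Ms4a3-Cre C1qc -0.60, Fcgr4 -0.092. In cDC2A-like cells alone after thinning, for CD300c-iCre Bcl11a -0.12, Cd14 0.14, Cd74 0.12 (0.00108), H2-Ab1 0.13 (8.7e-04), H2-D1 0.10, H2-Eb1 0.15 (5.7e-05), Il1b 0.33 (1.0e-11), Lgmn 0.27, Ms4a7 0.019, Nfkbia 0.14, Serpinb6b -0.16, Spic 0.47, Tmem176a 5.2e-04; for CD300c-iCre against IL-7R-Cre Cadm1 0.20, Cd74 0.12, Fcgr2b 0.19, H2-Ab1 0.12, Il1b 0.38 (4.8e-07), Lyz2 0.34, Ms4a7 0.11, Plin2 0.33, Sept1 -0.095, Serpinb6b -0.26, Sox4 -0.090, Tmem176a 0.37 (0.0288); for CD300c-iCre against Ms4a3-Cre H2-Eb1 0.064, Il1b 0.14; for IL-7R-Cre Cd74 0.0022; for Ms4a3-Cre Cox5a -0.035, Ifi27l2a -0.0034, Kdm5d 0.062, Rsad2 -0.14. In cDC2B/DC3-like cells alone, for lines in cDC2, IL-7R-Cre against Ms4a3-Cre Td_Tomato -0.40; for CD300c-iCre Crip1 0.43 (3.8e-04), H2-D1 0.0058, Il1b 0.017, Mast4 -0.12, Nfkbia 0.72 (6.0e-09), Uty -0.022; for CD300c-iCre against IL-7R-Cre Abcb1a -0.20, Cd74 0.013, Il1b 0.024, Sox4 -0.0077; for CD300c-iCre against Ms4a3-Cre Crip1 0.59 (5.2e-04), Hba-a1 -0.38, Il1b 0.022, Mast4 -0.091, Nfkbia 0.81 (7.8e-07); for IL-7R-Cre Ccr2 0.13, Crip1 0.17, Esrrg -1.08, Ncald -0.078, Prdm1 0.085; for IL-7R-Cre against Ms4a3-Cre Crip1 0.33, Esrrg -1.74; for Ms4a3-Cre Cd74 -0.0056, H2-D1 -0.012, Hba-a1 0.47, Hba-a2 0.56, Hspa1b -0.016, Nfkbia -0.096. In cDC2B/DC3-like cells alone after thinning, for CD300c-iCre Crip1 0.51 (3.0e-09), Il1b 0.15 (0.0148), Mast4 -0.22, Nfkbia 0.90 (1.4e-26), Uty -0.17; for CD300c-iCre against IL-7R-Cre Cd74 0.020, Il1b 0.17, Irf4 -0.32, Tmem176a 0.042; for CD300c-iCre against Ms4a3-Cre Ccdc192 -0.76, Crip1 0.69 (2.8e-08), Hba-a1 -0.45, Il1b 0.026, Nfkbia 0.90 (6.9e-15); for IL-7R-Cre Ccr2 0.16, Crip1 0.30 (0.0181), Cst3 0.036, Ltb4r1 0.10, Mcub 0.34; for IL-7R-Cre against Ms4a3-Cre Crip1 0.48 (0.003), Il7r -0.38, Mcub 0.011; for Ms4a3-Cre Ccdc192 0.55, Hba-a1 0.50, Spic -0.40. After thinning all cells, for cDC1 CD300c-iCre against IL-7R-Cre Cox7b 0.056, Pola1 -0.21; for cDC1 CD300c-iCre against Ms4a3-Cre Ptk2b -0.011; for cDC1 IL-7R-Cre Wipf1 0.045; for CD300c-iCre against IL-7R-Cre Cd74 0.0075, H2-Ab1 0.011, Il1b 0.045, Serpinb6b -0.098. Without cluster 1, for CD300c-iCre Nfkbia 0.15 (0.024). Without clusters 3 and 14, for cDC1 CD300c-iCre Rnf217 -0.089; for cDC1 CD300c-iCre against IL-7R-Cre Ccdc192 -0.0095; for cDC1 IL-7R-Cre Arhgap42 -0.44. Fewer cells enter each of these settings, which does not account for a call in the opposite direction, and the cause was not tested.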

Other observations

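The tests of this part were chosen after the data were seen. Of the classes not compared above, B cell-like cells held 71.9 ± 11.4 CPM of tdTomato in the CD300c-iCre line, 386 ± 106 CPM in the IL-7R-Cre line and 32.9 ± 9.07 CPM in the Ms4a3-Cre line (SD, n = 3 mice). T cell-like cells (43.3 ± 7.68, 335 ± 27.5 and 32.8 ± 5.96 CPM) and NK cell-like cells (56.5 ± 15.7, 456 ± 41.9 and 40.3 ± 0.548 CPM) had the same order of lines. Red pulp macrophage-like cells, which clear old red cells, held 294 ± 53.0, 249 ± 80.8 and 209.7 ± 143 CPM, with the mice of the Ms4a3-Cre line far apart. Non-classical monocyte-like cells were the reverse of the lymphoid classes, at 47.4 ± 7.35, 37.5 ± 14.2 and 329.7 ± 24.6 CPM. Proliferating cells, thinned to 3000 UMIs, were tdTomato-positive in 41.5% ± 2.74, 17.4% ± 2.76 and 7.88% ± 4.92. They pool cluster 12 (57.4%, 22.1% and 7.19%) with cluster 15 (15.6%, 11.4% and 9.40%), whose share was near the background and did not pass the test between lines (exact permutation p = 0.279).

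By cluster, the thinned tdTomato share within cDC2A-like cells ran from 56.0% (cluster 5) to 74.2% (cluster 21) in the CD300c-iCre line, from 27.4% to 41.3% in the IL-7R-Cre line and from 8.69% to 11.1% in the Ms4a3-Cre line. Among cDC2B/DC3-like cells, cluster 13 (cDC2B) was at 56.2%, 20.2% and 22.8% and cluster 2 (DC3) at 31.1%, 17.0% and 22.6% in the same order of lines, so that in the CD300c-iCre line cluster 13 was close to cluster 5.

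The axis on which mice of a line differed had the G-protein regulator Rgs1 and the heat shock genes Hspa1a, Hspa1b and Hsph1 at its high end and Homer1, Antxr2 and Stat4 at its low end. The pDC-like share of the mice was 14.7%, 18.6% and 28.7% in the CD300c-iCre line (axis scores of -0.069, -0.041 and 0.109), 14.1%, 34.6% and 13.5% in the IL-7R-Cre line (-0.057, 0.104 and -0.046) and 19.9%, 14.2% and 14.3% in the Ms4a3-Cre line (0.150, -0.064 and -0.086).

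Of genes that differed between the CD300c-iCre and Ms4a3-Cre lines in 3 classes, 13 lay within the first 10 Mb of chromosome 19, where 6.01 would be expected (permutation p over 277 windows = 0.0544 with all such genes, 0.0327 without those that NK and T cell RNA can give, 10000 permutations).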
